A study of Homo sapiens with 22 samples.

How the data were processed

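The gene tables deposited for 22 libraries were used, 4 from the siRNA and 18 from the actinomycin D experiment. Per the labels' protocols RNA was column-purified and libraries were stranded, from mRNA for the siRNA and total RNA for the actinomycin D experiment. Per the submitters' processing notes, reads were trimmed with cutadapt, aligned with STAR 2.7 and quantified with RSEM 1.3.1. The notes name hg38 for the siRNA libraries and hg19 for the actinomycin D libraries. The annotation release, the strand setting and any read filter are not given in the sources used here.

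Each deposited table, written by RSEM for the authors, held expected counts per gene, which divide a read that matches several genes among them and need not be whole. The authors' tables also held an effective length per gene, used here only as an offset in an alternative fit, and TPM values, which were not tested. Genes of near-identical sequence, such as histone copies, UGT2B15 with UGT2B17 and HIST2H3A with HIST2H3C, share reads in such counts, so their separate levels are uncertain. The 2 experiments differed in build, RNA selection and depth, so their levels were not compared. Short noncoding RNAs took 0.5 to 0.9% of siRNA and 16.6 to 25.7% of actinomycin D counts. Mitochondrial mRNAs took 0.76 to 0.91% and 0.05 to 0.16%.

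Groups were taken from the labels, with n = 2 for siCTRL and siSTAU1 and n = 3 for each line at 0, 2 and 4 h of actinomycin D. Comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 under R 4.3.3 (TMM scaling, filterByExpr by group, glmQLFit and glmQLFTest, two-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The siRNA fit used its 4 libraries (14073 genes, 2 residual degrees of freedom, common dispersion 0.00148). The actinomycin D fit used its 18 libraries in 6 groups (17256 genes, 12 residual degrees of freedom, common dispersion 0.00666), with contrasts for 2 h and 4 h against 0 h in each line, HCT116 against LS180 at 0 h, and the line difference of the 4 h change, which makes 7 comparisons in all. After a block of transcription the CPM are relative to the transcripts that remain, so the changes given are not absolute losses. Standard errors were the absolute log2 fold change divided by the square root of the F statistic. Because 2 h and 4 h share their 0 h libraries, their calls were not compared with each other.

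Tested in all were 28 gene lists, made from general knowledge: FOXA-dependent, goblet and secretory, enteroendocrine, enterocyte, stem cell and Wnt, xenobiotic, interferon, inflammatory, proliferation, p53 target, endoplasmic reticulum stress, cholesterol, mesenchymal transition, epithelial, hypoxia and glycolysis, Staufen-mediated decay target, Staufen and nonsense-mediated decay factor, immediate early, KRAB zinc finger, ribosomal protein, mitochondrially encoded, nuclear oxidative phosphorylation, replication-dependent histone, snoRNA host, secretory pathway, and fibroblast, immune and endothelial marker genes. Limma 3.58.1 tested lists with at least 3 measured genes against all other genes with camera at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera was also run with an estimated correlation, and fry beside it, which is not reported. Members were also counted after adjustment over the list alone. The text names STAU1, STAU2 and FOXA1 to FOXA3 everywhere, and up to 4 members with the smallest adjusted p in each list described. It also names the 8 largest rises and 8 largest falls per comparison among called genes averaging at least 5 CPM, leaving out pseudogenes and unnamed clones. Their libraries did not overlap between groups, which was not asked of the line difference. Members outside that rule, most of which went against their list, were chosen after their values were seen. So were genes named in the closing observations. Some list members that the rule names are not reported here.

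Where all libraries of a group were at 0, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with an exact binomial 95% interval. Gene coordinates came from a GRCh38 annotation matched on the identifier. Symbols are printed as the tables give them.

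Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, at least 1 CPM in every library of a group, effective length as an offset, the replicate number as a block, and each library left out in turn, where a lone library left in a group was assumed to vary like the others. For actinomycin D they were also a fit of only the groups compared, total library size without TMM, and scaling to ribosomal protein genes. After the data were seen, fits without the HCT116 libraries numbered 1, fits without the LS180 4 h libraries numbered 2 and 3, and the line difference of the 2 h change were added. Other computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

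The fits were tested on simulated data with 200 genes changed by known folds, far fewer than the real fits called. For the siRNA comparison (13925 genes) 80.6%, 91% and 100% of genes changed 1.5-, 2- and 4-fold were recovered, with 8.6% of calls false. For LS180 at 4 h (16630 genes) the shares were 76.1%, 94% and 98.5%, with 4.8% false, and for the line difference (16657 genes) 62.7%, 94% and 98.5%, with 4% false.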

Results

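The data were 22 RNA-seq libraries in 8 groups from a pair of human colorectal cancer cell lines, in a series on Staufen1 and the mRNA of the transcription factor FOXA1. In the first experiment LS180 cells, a mucin-producing adenocarcinoma line, received a control siRNA (siCTRL) or an siRNA against STAU1 (siSTAU1), a short RNA that guides cleavage of the matching mRNA, over a pair of 72 h periods. Each of these groups had n = 2 polyA-selected libraries, with 23.7 to 26.7 M counts (1 M is 1e6) per library. In the second experiment LS180 cells and HCT116 cells, a carcinoma line, received actinomycin D at 5 µg/ml, a compound that binds DNA and blocks transcription, for 0, 2 or 4 h. Each of those groups had n = 3 total RNA libraries, with 47.8 to 61.4 M counts per library. Levels are TMM-scaled CPM, a gene's counts relative to the scaled depth of its library, and are given as mean ± SD over the libraries of a group. The labels do not say whether libraries came from separate cultures, so p-values measure the spread between these samples, which may be technical. Intervals and floors cover counting error only.

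The comparison of siSTAU1 with siCTRL asked which mRNAs changed level in LS180 cells with less STAU1. STAU1 itself, which encodes a protein that binds RNA duplexes (ENSG00000124214; chromosome 20, 49113339 to 49188367, minus strand, GRCh38), stood at 144 and 141 CPM in the siCTRL libraries and at 9.70 and 9.17 CPM in the siSTAU1 libraries. It fell 15.1-fold (log2 fold change -3.92, SE 0.0571; edgeR adjusted p = 2.15e-12), which left 6.62% of the siCTRL level. STAU2, its paralog (ENSG00000040341), rose 1.20-fold, from 41.7 ± 0.201 to 49.9 ± 1.76 CPM (edgeR adjusted p = 0.00333). That call was lost with an effective length offset (log2 fold change 0.29, edgeR adjusted p = 0.0685; 0.00224 to 0.0685 over all alternatives).

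FOXA1 (ENSG00000129514; chromosome 14, 37589984 to 37596059, minus strand, GRCh38) rose 1.10-fold, from 63.9 ± 0.895 to 70.5 ± 0.307 CPM (log2 fold change 0.14, SE 0.047; edgeR adjusted p = 0.027). Its family member FOXA3 (ENSG00000170608) rose 1.34-fold, from 21.8 ± 0.653 to 29.1 ± 0.471 CPM (edgeR adjusted p = 0.000318). FOXA2 (ENSG00000125798) fell 1.35-fold, from 15.5 ± 0.417 to 11.5 ± 0.91 CPM (edgeR adjusted p = 0.00169). The FOXA1 estimate stayed between 0.13 and 0.17 under every alternative tried, but its adjusted p ranged from 0.0193 to 0.185 in edgeR and DESeq2. The call was lost with DESeq2 (0.114), with an effective length offset (0.0633), without a filter on low counts (0.0613), and without siCTRL library 1 (0.185), siCTRL library 2 (0.109), siSTAU1 library 1 (0.0765) or siSTAU1 library 2 (0.0728).

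**Figure D1:**
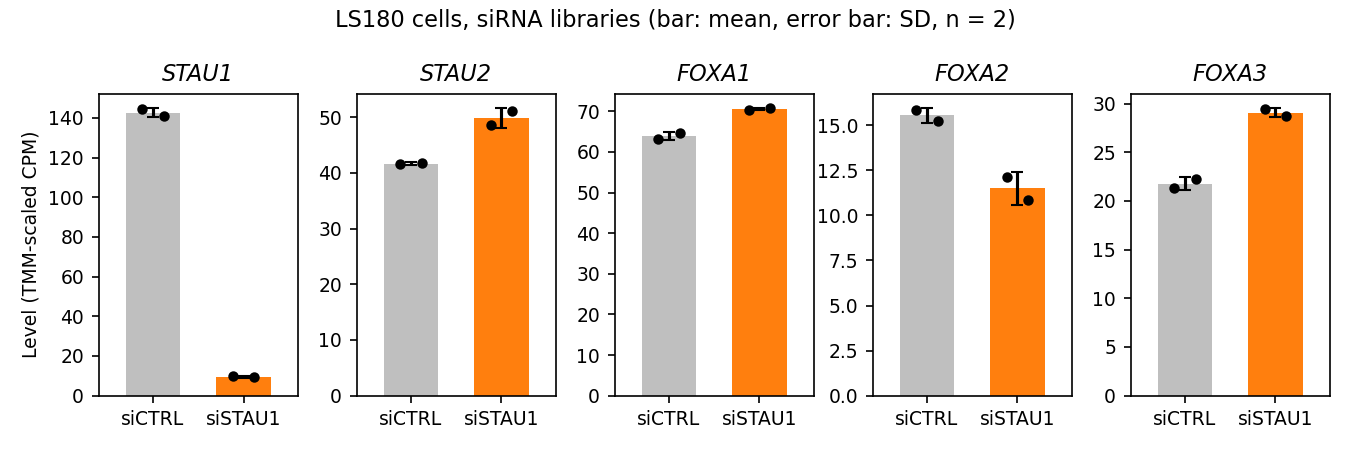
TMM-scaled CPM of STAU1, STAU2, FOXA1, FOXA2 and FOXA3 in the siCTRL and siSTAU1 libraries of LS180 cells (bars, mean; error bars, SD; n = 2; points, libraries). STAU1 fell from 143 to 9.44 CPM, and FOXA1 stood at 63.9 and 70.5 CPM.

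Among ranked genes averaging at least 5 CPM, the largest rise was in LUM, which encodes the extracellular matrix proteoglycan lumican. LUM rose 6.62-fold from 1.49 ± 0.341 CPM (log2 fold change 2.73, SE 0.175; edgeR adjusted p = 4.52e-07). The glucuronosyltransferase gene UGT2B15 rose 3.74-fold (4.91 ± 0.569 to 18.4 ± 0.923 CPM) and its near-identical paralog UGT2B17 rose 3.59-fold (4.14 ± 0.168 to 14.9 ± 1.20 CPM). Expected counts can divide reads between this pair, so their separate levels are uncertain. ENTPD8, an ectonucleotidase gene, rose 3.12-fold to 24.2 CPM, and PRLR, the prolactin receptor gene, rose 3.04-fold to 25.5 CPM. MAPK8IP1, TM4SF4 and RARRES1 rose by 1.54, 1.52 and 1.43 on the log2 scale.

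After STAU1, the ranked gene with the largest fall was ADAM19, a membrane metalloprotease gene. It fell 5.96-fold from 71.1 ± 1.16 to 11.9 ± 0.313 CPM (SE of the log2 fold change 0.0661; edgeR adjusted p = 7.63e-10). LCK, a tyrosine kinase gene, fell 4.67-fold, from 10.3 ± 0.514 to 2.21 ± 0.279 CPM, and PRDM8 fell 3.77-fold. GATD1 fell 2.95-fold to 13.1 CPM, and KMT5A, which encodes a histone H4 lysine methyltransferase, fell 2.87-fold to 19.8 CPM. VMA21, an assembly factor gene of the vacuolar ATPase, fell 2.58-fold from 66.2 to 25.7 CPM, and the keratin gene KRT4 had a log2 fold change of -1.42.

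Goblet and secretory genes, which encode mucins and the peptides secreted with them, mostly rose with siSTAU1. Of 25 tested, 18 rose and 3 fell (18 and 4 adjusted over the list alone), with a median log2 fold change of 0.39. REG4 rose from 428 ± 11.4 to 1083 ± 37.2 CPM, AGR2 from 1832 ± 32.6 to 3051 ± 81.6 CPM and TFF1 from 108 to 207 CPM. CLCA1 (log2 fold change -2.92, to 0.14 CPM), MUC13 (-0.33) and ZG16 (-0.29) fell. Limma's camera called the list at its preset correlation of 0.01 (adjusted p = 8.85e-13). With an estimated correlation, which 2 residual degrees of freedom set poorly, adjusted p was 0.297.

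The list of FOXA-dependent genes, fixed from general knowledge, had a median of 0.25. Of 14 members 8 were higher and 3 lower (8 and 3 adjusted over the list alone). SHH, a secreted morphogen gene, rose by 1.22 on the log2 scale, SPDEF, a goblet cell transcription factor gene, by 0.87 and TFF3 by 0.53. Among those that fell were HNF4A (-0.47) and KRT18 (-0.18). Camera gave an adjusted p of 9.92e-06, or 0.297 with an estimated correlation. TFF1, TFF3, AGR2 and SPDEF were also in the goblet list, so the lists were not independent.

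Xenobiotic metabolism and transport genes had 11 of 19 members higher and 2 lower (11 and 2 adjusted over the list alone), with a median of 0.24. The drug efflux transporter genes ABCB1 and ABCC3 rose by 1.28 and 1.21 on the log2 scale and CYP1A1 by 1.88. The nuclear receptor gene RXRA (-0.19) and the aryl hydrocarbon receptor gene AHR (-0.14) fell. Camera's adjusted p was 9.92e-06, or 0.297 with an estimated correlation.

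Ribosomal protein genes moved by small amounts in the same direction. Of 78 tested, 59 rose and 0 fell (63 and 0 adjusted over the list alone) at a median of 0.20, with RPL41 at 0.46 and RPL15 at 0.37. The ribosomal protein list had a camera adjusted p of 5e-11 (0.56 with an estimated correlation). Secretory pathway genes had 24 of 40 higher and 6 lower (24 and 7 adjusted over the list alone) at a median of 0.15. KDELR3 (0.89) and KDELR2 (0.59), receptors that return proteins to the endoplasmic reticulum, rose, and SEC23A (-1.13), a vesicle coat gene, fell. The secretory pathway list had a camera adjusted p of 0.00091 (0.297 with an estimated correlation). Mesenchymal transition genes had 6 of 10 higher and 1 lower (6 and 1 adjusted over the list alone) at a median of 0.71. TAGLN was at 0.95, CCN2 at 0.94 and TGFBI at 0.73 among the higher, and TGFB2 (-0.56) was lower. The mesenchymal list had a camera adjusted p of 0.00187 (0.297 with an estimated correlation). Both LUM and the collagen gene COL3A1 (5.30 ± 0.442 against 2.51 ± 0.0529 CPM) of the 3 fibroblast markers tested rose (2 and 0 adjusted over the list alone), and PDGFRB was not called (-0.30, edgeR adjusted p = 0.616). That list, with a median of 1.08, had a camera adjusted p of 0.0149 (adjusted p = 0.297 with an estimated correlation), which rose to 0.113 without a filter on low counts and ranged from 0.00831 to 0.113.

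Genes of cholesterol synthesis mostly fell, with 14 of 25 lower and 4 higher (15 and 5 adjusted over the list alone) and a median of -0.12. The pathway enzyme genes MVD, LSS and HMGCS1 fell by 0.84, 0.63 and 0.59 on the log2 scale. The cholesterol list had a camera adjusted p of 0.000293 (0.297 with an estimated correlation). Of 27 hypoxia and glycolysis genes 16 fell and 0 rose (16 and 0 adjusted over the list alone) at a median of -0.17. Among the lower were ALDOC (-0.81), EGLN3 (-0.57), PFKFB3 (-0.47) and GPI (-0.30). The hypoxia list had a camera adjusted p of 0.00091 (0.297 with an estimated correlation). The list of Staufen partners and nonsense-mediated decay factors had 11 of 20 members lower and 5 higher (12 and 5 adjusted over the list alone) at a median of -0.18. SMG5 fell from 157 to 66.9 CPM, SMG9 (-0.96) and UPF1 (-0.63) fell, and PNRC2 (0.44) rose. The Staufen factor list had a camera adjusted p of 0.0149 (0.347 with an estimated correlation). Stem cell and Wnt target genes had 8 of 20 lower and 4 higher (10 and 5 adjusted over the list alone) at a median of -0.14. OLFM4 (-0.81), MYC (-0.46) and EPHB3 (-0.36) were lower and ASCL2 (0.33) higher. The stem cell list had a camera adjusted p of 0.0243 (adjusted p = 0.452 with an estimated correlation).

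**Figure D2:**
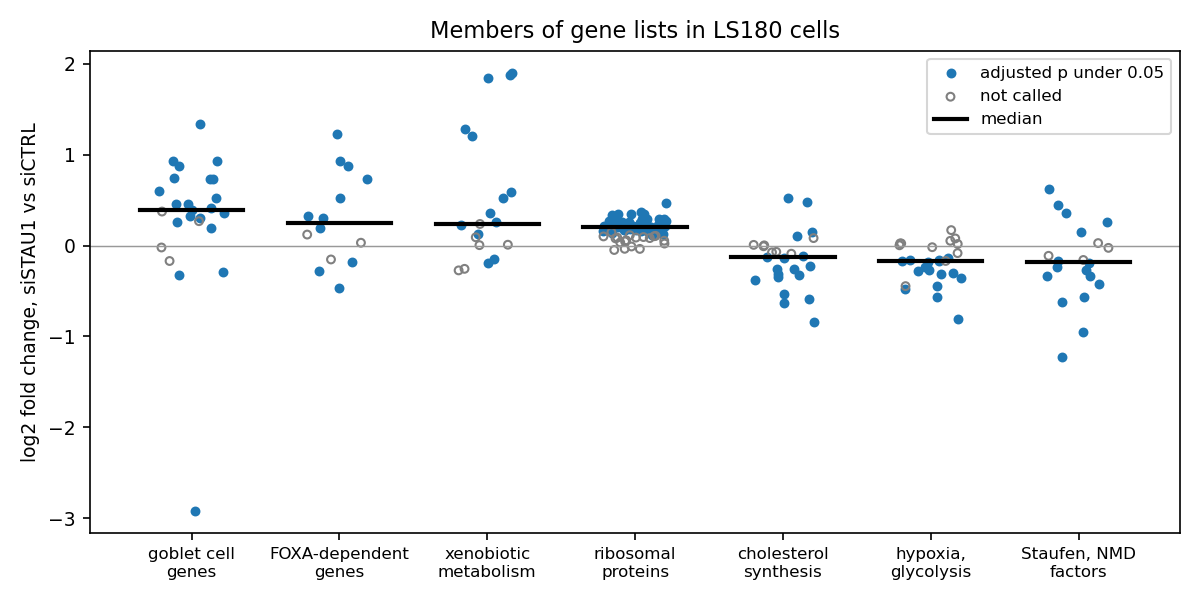
Log2 fold change, siSTAU1 against siCTRL in LS180 cells (n = 2 each), of each tested member of 7 gene lists (points; filled where the edgeR adjusted p was under 0.05; line, median). Medians ran from 0.39 for goblet genes to -0.18 for the Staufen and decay factors.

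Calls for 3 further lists depended on the processing or on single libraries. The p53 target list had 12 of 29 members higher, among them TP53I3 (1.14) and GDF15 (0.93), and 5 lower (13 and 5 adjusted over the list alone) at a median of 0.07. Its camera adjusted p of 0.0343 (adjusted p = 0.297 with an estimated correlation) became 0.0624 without siCTRL library 2 and 0.0978 without siSTAU1 library 1, within a range of 0.0232 to 0.0978. The snoRNA host list had 7 of 17 higher and 4 lower (8 and 4 adjusted over the list alone), with H19 at 1.43, SNHG5 at 0.65 and GAS5 at 0.43. Its median was 0.07 and its camera adjusted p was 0.0243 (adjusted p = 0.452 with an estimated correlation), against 0.0641 with an effective length offset and a range of 0.0102 to 0.0641. The immediate early list had 17 of 44 higher, including the chemokine gene CXCL8 (1.41) and JUN (0.84), and 7 lower (18 and 7 adjusted over the list alone) at a median of 0.16. Its camera adjusted p of 0.0382 (adjusted p = 0.297 with an estimated correlation) became 0.0641 with an effective length offset and 0.102 without siSTAU1 library 1, within a range of 0.0179 to 0.102.

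The other lists were not called by camera. Of 5 genes listed as Staufen-mediated decay targets 4 rose and 0 fell (4 and 0 adjusted over the list alone). The 4 included JUN (0.84, also an immediate early gene), KLF2 (0.53) and ARF1 (0.12). The list's median was 0.53 and its camera adjusted p was 0.0541 (adjusted p = 0.345 with an estimated correlation), with a range of 0.0179 to 0.0968 over the alternatives. It was called without a filter on low counts (0.0179) and without siCTRL library 1 (0.0489), siCTRL library 2 (0.0439) or siSTAU1 library 1 (0.0499). Interferon response genes had 9 of 35 higher, including OAS1 (0.64) and ISG15 (0.62), and 3 lower (9 and 3 adjusted over the list alone) at a median of 0.08 (camera adjusted p = 0.275). Enterocyte genes had 11 of 21 higher, with CDHR5 at 0.69, and 6 lower, with PHGR1 at -0.42 (11 and 6 adjusted over the list alone), at a median of 0.20 (camera adjusted p = 0.283). Proliferation genes had 15 of 35 higher, with RRM2 at 0.51, and 9 lower (16 and 10 adjusted over the list alone), at a median of 0.01. Their camera adjusted p was 0.0872 and ran from 0.0355, without siSTAU1 library 2, to 0.163 over the alternatives.

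Nuclear genes of oxidative phosphorylation had 26 of 63 higher, with NDUFB2 at 0.52, and 10 lower, with NDUFS1 at -0.47 (28 and 10 adjusted over the list alone). Their median was 0.10 and their camera adjusted p was 0.126, against 0.0106 without siSTAU1 library 1 and 0.0239 without a filter on low counts, in a range of 0.0106 to 0.517. Mitochondrially encoded genes had 3 of 13 higher, with MT-ND3 at 0.33, and 3 lower, with MT-ATP8 at -0.30 (3 and 3 adjusted over the list alone). Their median of -0.12 (camera adjusted p = 0.758) became -0.22 without siSTAU1 library 1 (camera adjusted p = 0.0106, in a range of 0.0106 to 0.774). The test pointed up without siCTRL library 2 (-0.013) or siSTAU1 library 2, where the median was 0.035. Of 52 KRAB zinc finger genes 2 were higher and 10 lower, among them ZNF274 (-0.52) and ZNF37A (-0.45), or 0 and 6 adjusted over the list alone, at a median of -0.13 (camera adjusted p = 0.239). Of 13 replication-dependent histone genes 3 were higher, including HIST1H2AC (0.62), and 0 lower (3 and 0 adjusted over the list alone) at a median of 0.34 (camera adjusted p = 0.413). It became -0.058 without siSTAU1 library 2, and 0.010 without siCTRL library 2, where the test pointed down. Reads of histone copies can be divided among them, and polyA selection recovers their mRNAs poorly.

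Endoplasmic reticulum stress genes had 10 of 33 higher and 11 lower (10 and 13 adjusted over the list alone), with DNAJB9 at 0.58 and SLC7A11 at -0.73. Their median of 0.03 differed in sign from their mean of -0.02 and from the direction of the test, which was down (camera adjusted p = 0.816), and turned to -0.048 without siSTAU1 library 2. Epithelial genes had 8 of 22 higher and 6 lower (9 and 9 adjusted over the list alone), and CDH1, the E-cadherin gene, fell from 454 to 244 CPM. Their median was 0.04 and their mean 0.05, while the test pointed down (camera adjusted p = 0.816). Inflammatory genes had 6 of 19 higher and 5 lower (6 and 5 adjusted over the list alone), with CXCL8 at 1.41 and BIRC3 at -0.47. Their median of -0.13 was of opposite sign to their mean of 0.07 and to the test, which pointed up (camera adjusted p = 0.561). Of the 3 enteroendocrine genes tested edgeR called 0 higher and 0 lower (0 and 0 adjusted over the list alone) at a median of 0.12 (camera adjusted p = 0.816). Among markers of other cell types, LYZ fell from 227 ± 7.12 to 91.0 ± 1.15 CPM and CD14 rose from 2.81 to 4.00 CPM in the immune list of 2. ERG, from the endothelial list, was not called (-0.18, edgeR adjusted p = 0.571).

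Of 14073 genes tested, 3242 rose and 3240 fell with siSTAU1 (edgeR adjusted p under 0.05), and 220 and 162 of these changed at least 2-fold. The counts were 2248 higher and 2159 lower with an effective length offset and 1968 and 2105 without siCTRL library 1. Camera called 14 of 26 lists at the preset correlation. It called 0 with an estimated one (smallest adjusted p = 0.297), which 2 residual degrees of freedom leave too uncertain to decide the calls.

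Actinomycin D treatment of LS180 cells asked how much of each transcript was left, relative to the other transcripts, after transcription was blocked. FOXA1 fell from 38.6 ± 1.78 CPM at 0 h to 8.54 ± 0.168 at 2 h and 3.59 ± 0.828 at 4 h (n = 3). The fall was 4.52-fold at 2 h (SE of the log2 fold change 0.142; edgeR adjusted p = 3.83e-10) and 10.7-fold at 4 h (SE 0.156; edgeR adjusted p = 1e-12). FOXA2 fell by 13.2-fold and 22.4-fold from 9.42 ± 0.573 CPM, and FOXA3 by 7.21-fold and 17.6-fold from 6.67 ± 0.547 CPM. Over all alternatives the 4 h log2 change of FOXA1 lay between -3.95 and -2.71. STAU1 stood at 72.9 ± 2.12, 81.0 ± 3.23 and 83.6 ± 5.21 CPM at 0, 2 and 4 h (log2 changes 0.15, edgeR adjusted p = 0.0299, and 0.20, edgeR adjusted p = 0.00342). STAU2 stood at 41.7 ± 2.59, 44.7 ± 0.747 and 49.7 ± 3.36 CPM (0.10, edgeR adjusted p = 0.21, and 0.25, edgeR adjusted p = 0.00151). Scaled to ribosomal protein genes, the log2 changes of STAU1 were -0.08 and -0.34 (edgeR adjusted p = 0.652 and 0.0132) and those of STAU2 -0.13 and -0.30 (edgeR adjusted p = 0.198 and 0.00189). With total library size the 4 h calls were lost (edgeR adjusted p = 0.99 for STAU1 and 0.631 for STAU2). The 2 h call of STAU1 was also lost with total library size (edgeR adjusted p = 0.398), and with an effective length offset (0.0574). It was lost as well without 0 h library 2 (edgeR adjusted p = 0.075), 0 h library 3 (0.104), 2 h library 1 (0.0555) or 2 h library 3 (0.131), within a range of 2.06e-06 to 0.652. The 2 h change of STAU2 was called without 2 h library 2 (0.23, edgeR adjusted p = 0.0131). It was also called with RLE size factors, DESeq2, no filter on low counts, or at least 1 CPM in every library of a group (adjusted p from 0.00144 to 0.0103).

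Among the largest falls in LS180 cells, MYC, a transcription factor gene, fell 30.7-fold by 2 h and 57.3-fold by 4 h, from 249 ± 20.8 to 8.10 ± 0.808 and 4.33 ± 0.355 CPM. DUSP6, SPRY2, NFKBIA and DDIT4, inhibitors of ERK, receptor kinase, NF-kB and mTOR signalling, changed by -4.79, -4.50, -4.42 and -4.35 on the log2 scale at 2 h. At 4 h the TNF ligand gene TNFSF9 (-5.42) and the ephrin receptor gene EPHB3 (-5.16, from 333 ± 45.4 to 9.28 ± 2.94 CPM) were also among the 8 largest falls. The histone genes HIST1H1D (-4.92, or -5.53 without 2 h library 1, and -6.68) and HIST1H2BJ (-4.88 and -6.01) fell at both times, and HIST1H4B (-5.80), HIST1H3A (-5.60) and HIST1H2BG (-5.54) were among the largest falls at 4 h. Near-identical histone copies can share reads, so the split among them is uncertain.

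The top rises included small nucleolar and mitochondrial RNAs. SNORD13 rose 2.27-fold by 2 h and 3.34-fold by 4 h (12.1 ± 2.76, 27.3 ± 5.67 and 40.4 ± 11.7 CPM), and SNORA8 2.16-fold and 3.06-fold. The mitochondrial ribosomal RNAs MT-RNR1 (0.94 and 1.43) and MT-RNR2 (0.76 and 1.21), MT-CYB (0.63 and 1.20) and MT-ND4 (0.66 and 1.23) rose at both times, and MT-ATP6 (1.11) and MT-ND5 (1.04) were among the largest rises at 4 h. The nuclear noncoding RNA MALAT1 (0.66) and SLC25A29 (0.67) rose at 2 h. With scaling to ribosomal protein genes the 2 h calls of MALAT1 (edgeR adjusted p = 0.081) and MT-ND4 (0.0909) were lost.

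By list, 43 of 44 immediate early genes fell and 1 rose at 2 h, and again at 4 h (1 and 43 adjusted over the list alone at both times), with medians of -2.32 and -3.08. MYC, DUSP6 and IER3 (-4.09 and -4.55) led them, and FOSB was the member that rose (1.62 and 2.84, from 0.441 ± 0.044 to 3.18 ± 1.09 CPM at 4 h). Of 55 KRAB zinc finger genes 52 fell at 2 h (0 higher and 53 lower adjusted over the list alone). At 4 h 53 fell and 1, ZNF124, rose (1 and 53 adjusted over the list alone). Their medians were -1.29 and -1.80, with ZNF14 at -4.13 and -4.15. Both lists kept their camera calls with an estimated correlation at 2 h (adjusted p = 0.00111 and 0.00105) and at 4 h (0.00876 and 0.00607). All 19 histone genes fell at both times (0 and 19 adjusted over the list alone), at medians of -3.17 and -4.28. The histone list had a camera adjusted p of 1.31e-15 and 3.38e-12 (0.125 and 0.236 with an estimated correlation). The p53 targets had 18 of 30 lower and 1 higher at 2 h (18 and 1 adjusted over the list alone). At 4 h 20 were lower and 4 higher (21 and 4 adjusted over the list alone), with BTG2 at -3.54 and -4.38. The p53 target list had a camera adjusted p of 4.92e-08 and 1.11e-06 (0.355 and 0.43 with an estimated correlation).

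Stem cell and Wnt target genes had 10 of 22 lower at 2 h with 0 higher, and 10 lower with 3 higher at 4 h (the same counts adjusted over the list alone), with AXIN2 at -3.69 and -4.64. Their 2 h median of -0.03 became 0.09 with RLE size factors, 0.10 without a filter on low counts and 0.08 with at least 1 CPM in every library of a group, and 0.10 without 2 h library 2. The mean was -0.99 and the camera adjusted p was 1.78e-06 at 2 h and 1.95e-06 at 4 h (adjusted p = 0.125 and 0.196 with an estimated correlation). Inflammatory genes had 11 of 18 lower and 2 higher at 2 h (13 and 3 adjusted over the list alone). At 4 h 12 were lower and 3 higher (12 and 3 adjusted over the list alone), with NFKBIA at -4.42 and -4.62. The inflammatory list had a camera adjusted p of 4.59e-06 and 0.00206 (0.0632 and 0.236 with an estimated correlation). Of the 5 Staufen-mediated decay targets 4 fell and 1, ARF1 (0.19), rose at 2 h. Those that fell included JUN (-2.96, also an immediate early gene), KLF2 (-2.61) and SOWAHC (-1.34). The counts were the same at 4 h, when ARF1 was at 0.38 (4 lower and 1 higher adjusted over the list alone at both times). Camera gave adjusted p = 0.00662 and 0.0408 for them (adjusted p = 0.0632 and 0.196 with an estimated correlation). Their 4 h call was lost without 4 h library 1 (camera adjusted p = 0.0746), without a filter on low counts (0.0802) and with at least 1 CPM in every library of a group (0.0944), in a range of 0.00268 to 0.0944. Endoplasmic reticulum stress genes had 13 of 33 lower and 9 higher at 2 h (13 and 11 adjusted over the list alone) with DDIT4 at -4.35 and CEBPB at -1.85. Their camera adjusted p of 0.034 (adjusted p = 0.191 with an estimated correlation) became 0.107 without 2 h library 2, 0.0883 with RLE size factors, 0.79 without a filter on low counts and 0.182 with at least 1 CPM in every library of a group. Under these their median of -0.04 turned positive.

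Ribosomal protein genes were higher in 50 of 78 at 2 h with 0 lower (59 and 0 adjusted over the list alone), and in 77 with 0 lower at 4 h (77 and 0 adjusted over the list alone). Their medians were 0.24 and 0.58, with RPS27 at 0.37 and 0.72. Nuclear genes of oxidative phosphorylation were higher in 47 of 63 and then 62, with 1 lower at each time, NDUFV3 at -0.29 and -0.80 (54 and then 62 higher and 1 lower adjusted over the list alone). Their medians of 0.22 and 0.51 became -0.01 and -0.05 with scaling to ribosomal protein genes. Secretory pathway genes were higher in 28 of 40 and then 36 with 0 lower (34 and 37 adjusted over the list alone), at medians of 0.20 and 0.41 that became -0.03 and -0.14 with that scaling. Camera's adjusted p at 4 h was 1.3e-14, 1.17e-11 and 1.32e-08 for these 3 lists (adjusted p = 0.438, 0.438 and 0.276 with an estimated correlation). At 2 h it was 4.92e-08, 4.78e-07 and 6.36e-06 (adjusted p = 0.591, 0.58 and 0.37 with an estimated correlation). Goblet genes had 11 of 26 higher at 4 h, with SPINK4 at 0.68 and both TFF3 and REG4 at 0.58, and 3 lower, with ATOH1 at -4.34 (11 and 3 adjusted over the list alone). Their median of 0.39 became -0.16 with scaling to ribosomal protein genes. Their camera adjusted p of 0.0481 (adjusted p = 0.43 with an estimated correlation; range 0.00181 to 0.15) was lost without 0 h library 2 (0.0509), 0 h library 3 (0.0782), 4 h library 1 (0.068) or 4 h libraries 2 and 3 together (0.051). RLE size factors (camera adjusted p = 0.0812), an effective length offset (0.0502) and at least 1 CPM in every library of a group (0.15) ended it too.

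Of 17256 genes tested in LS180 cells, 2329 rose and 4121 fell by 2 h, and 4591 rose and 5365 fell by 4 h (edgeR adjusted p under 0.05). At 2 h the share of higher calls was 36.1% as fitted, 59.1% with RLE size factors (4863 and 3364), 60% with DESeq2 (4927 and 3284) and 63.7% with at least 1 CPM in every library of a group (5189 and 2961). It was 22.4% with total library size (1095 and 3797) and 1% with scaling to ribosomal protein genes (55 and 5631). At 4 h the share was 46.1% as fitted, 56.7% with RLE size factors (6044 and 4613) and 56.3% without 4 h libraries 2 and 3 (4683 and 3637). With the TMM reference kept, not chosen anew, it was 40.1% (2800 and 4181). With total library size it was 22.7% (1893 and 6460), and with scaling to ribosomal protein genes 1.2% (132 and 10737). RLE size factors moved the median of all genes by 0.119 and 0.131 at the 2 times, scaling to ribosomal protein genes by -0.233 and -0.544, and total library size by -0.199 at 4 h. Changes smaller than these shifts had a direction only relative to the scaling.

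**Figure D3:**
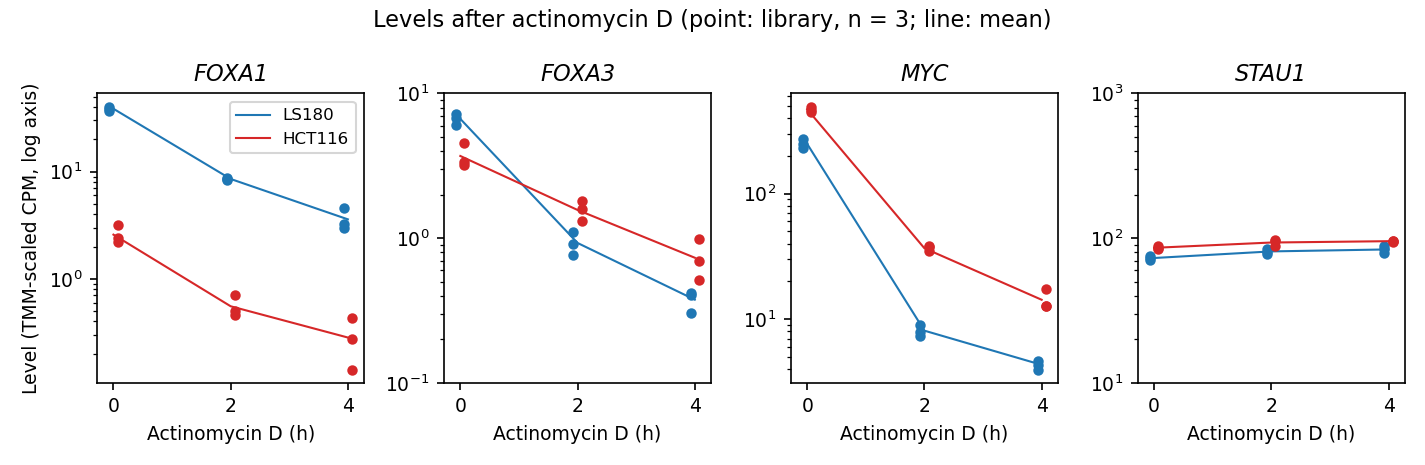
TMM-scaled CPM (log axis) of FOXA1, FOXA3, MYC and STAU1 at 0, 2 and 4 h of actinomycin D in LS180 and HCT116 cells (points, libraries, n = 3; line, mean). FOXA1 went from 38.6 to 3.59 CPM in LS180 and from 2.58 to 0.283 CPM in HCT116.

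HCT116 cells, with less FOXA1, were treated alike. FOXA1 fell from 2.58 ± 0.52 to 0.555 ± 0.128 CPM at 2 h and 0.283 ± 0.145 CPM at 4 h (n = 3). It was 4.69-fold lower at 2 h (SE of the log2 fold change 0.227; edgeR adjusted p = 3.82e-07) and 8.97-fold lower at 4 h (SE 0.257; edgeR adjusted p = 7.55e-09). FOXA3 fell by 2.37-fold and 5.01-fold from 3.70 ± 0.742 CPM. FOXA2 had 8 counts over the 0 h libraries and 0 at 2 and 4 h, at least 2.58-fold and 2.60-fold lower against a floor of 3 counts over the group. Its calls were lost without 0 h library 1 (edgeR adjusted p = 0.138 and 0.0963). STAU1 stood at 85.8 ± 2.04, 93.3 ± 4.55 and 95.3 ± 0.503 CPM (log2 changes 0.12, edgeR adjusted p = 0.0873, and 0.15, edgeR adjusted p = 0.021). STAU2 stood at 29.4 ± 1.98, 33.0 ± 0.395 and 35.3 ± 1.14 CPM (0.17, edgeR adjusted p = 0.0491, and 0.26, edgeR adjusted p = 0.00149). With scaling to ribosomal protein genes these log2 changes were -0.09 and -0.24 for STAU1 and -0.05 and -0.12 for STAU2. The 4 h call of STAU1 was lost without 0 h library 1 (edgeR adjusted p = 0.0654) or 4 h library 1 (0.0729), 2 (0.173) or 3 (0.159), within a range of 0.000665 to 0.811. Its 2 h change was called without 2 h library 1 (edgeR adjusted p = 0.0397) and with DESeq2 (0.0261). The 2 h call of STAU2 was lost without 0 h library 2 (edgeR adjusted p = 0.147), 0 h library 3 (0.178), or 2 h library 1 (0.108), 2 (0.162) or 3 (0.143), within a range of 0.0158 to 0.766. Its 4 h call was lost with total library size (edgeR adjusted p = 0.127).

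Replication-dependent histone genes made up the 8 largest falls in HCT116 cells at both times. HIST1H3J fell 247-fold by 4 h, from 220 ± 26.5 to 0.882 ± 0.165 CPM, and HIST1H4B fell 144-fold. HIST1H2BJ (-6.03 at 2 h and -6.86 at 4 h), HIST1H2AD (-5.18 and -6.85) and HIST1H2BO (-5.20 and -6.67) fell at both times. HIST2H3A (-5.94, with 3.53 ± 6.12 CPM at 2 h, all in library 2), HIST2H3D (-5.03) and HIST2H2BE (-4.94) were among the largest falls at 2 h, and HIST1H2AH (-6.55), HIST1H2AI (-6.53) and HIST1H3H (-6.50) at 4 h, with the same doubt over shared reads. The largest rise was in MT-RNR1, by 2.36-fold and 2.46-fold, followed by MT-CO3 (1.03 and 1.12), SNORD13 (1.01 and 1.00), MT-RNR2 (0.91 and 0.97) and MT-ND4 (0.77 and 0.92), with MT-CO1 at 0.66 and 0.76. At 2 h NEAT1 (0.83) and MALAT1 (0.65), nuclear RNAs, also rose. With scaling to ribosomal protein genes they had edgeR adjusted p = 0.064 and 0.0954, and NEAT1 had a log2 change of -0.59 with an effective length offset. At 4 h GRB14 rose by 0.88 and MRPL30 by 0.77. That of MRPL30 was not called without 0 h library 1 (edgeR adjusted p = 0.0964), 4 h library 3 (0.194) or the libraries numbered 1 (0.0903), with total library size (0.0604) and with scaling to ribosomal protein genes (0.295), the highest of its alternatives.

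Immediate early genes fell in 42 of 44 with 0 higher at 2 h (0 and 42 adjusted over the list alone). At 4 h 43 fell and 1, FOSB at 1.01, rose (1 and 43 adjusted over the list alone). Their medians were -1.98 and -2.49, with MYC at -3.68 and -5.04 and IER3 at -3.71 and -4.45. KRAB zinc finger genes fell in 43 of 55 with 2 higher (2 and 43 adjusted over the list alone) and then in 44 with 2 higher (2 and 44 adjusted over the list alone), at medians of -0.77 and -1.27. Both lists kept their camera calls with an estimated correlation (adjusted p = 0.000394 and 0.000997 at 2 h, 0.000232 and 0.00142 at 4 h). So did the Staufen-mediated decay targets at 2 h (adjusted p = 0.0419) but not at 4 h (camera adjusted p = 0.00656; adjusted p = 0.079 with an estimated correlation). Of those 5 genes 3 fell and 1 rose at each time (3 and 1 adjusted over the list alone), with KLF2 at -2.20 and -3.67 and ARF1 at 0.17 and 0.30. Of the histone genes 16 of 19 fell at both times (16 and 17 adjusted over the list alone), with HIST1H2AC at -3.79 and -4.18. The histone list had a camera adjusted p of 1.82e-25 and 3.34e-19 (adjusted p = 0.0544 and 0.122 with an estimated correlation).

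The p53 targets had 14 of 30 lower and 2 higher at 2 h (15 and 2 adjusted over the list alone). At 4 h 18 were lower and 5 higher (18 and 6 adjusted over the list alone), with SESN2 at -2.24 and -3.46. The p53 target list had a camera adjusted p of 9.98e-07 and 1e-06 (adjusted p = 0.433 and 0.408 with an estimated correlation). Stem cell and Wnt target genes had 9 of 22 lower at both times, with 0 and then 2 higher (the same counts adjusted over the list alone), and AXIN2 was at -2.51 and -3.09. Their medians of -0.75 and -0.45 became -0.11 and -0.32 with genes at 0 counts set to their bound. The stem cell list had a camera adjusted p of 9.98e-07 and 6.24e-06 (adjusted p = 0.107 and 0.177 with an estimated correlation). Inflammatory genes had 9 of 18 lower and 2 higher at 2 h (9 and 3 adjusted over the list alone). At 4 h 11 were lower and 3 higher (11 and 3 adjusted over the list alone), with NFKBIA at -3.03 and -3.88. The inflammatory list had a camera adjusted p of 0.000156 and 0.00895 (adjusted p = 0.107 and 0.307 with an estimated correlation). The 4 h call was lost with an effective length offset (0.0663, in a range of 0.00424 to 0.0663). Endoplasmic reticulum stress genes had 14 of 33 lower and 11 higher at 2 h (14 and 11 adjusted over the list alone). At 4 h 13 were lower and 13 higher (14 and 13 adjusted over the list alone), with DDIT4 at -2.97 and -3.74. The stress list had a camera adjusted p of 0.00925 and 0.0283 (adjusted p = 0.107 and 0.226 with an estimated correlation). Both calls were lost without a filter on low counts (camera adjusted p = 0.111 and 0.292), and the 4 h call with at least 1 CPM in every library of a group (0.0897).

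Ribosomal protein genes were higher in 49 of 78 and then 77, with RPS17L lower at each time (59 and then 77 higher and 1 lower adjusted over the list alone), at medians of 0.23 and 0.41. Oxidative phosphorylation genes were higher in 43 of 63 and then 62, with NDUFV3 lower at each time (52 and then 62 higher and 1 lower adjusted over the list alone), at medians of 0.24 and 0.45. Secretory pathway genes were higher in 27 of 40 and then 35 with 0 lower (31 and 35 adjusted over the list alone), at medians of 0.21 and 0.34 that became -0.01 and -0.05 with scaling to ribosomal protein genes. Camera gave these 3 lists adjusted p = 6.5e-08, 1.17e-07 and 8.55e-07 at 2 h (adjusted p = 0.678, 0.619 and 0.357 with an estimated correlation). At 4 h camera's adjusted p was 1.98e-10, 6.24e-11 and 2.82e-07 (adjusted p = 0.643, 0.57 and 0.319 with an estimated correlation).

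In HCT116 cells 2389 of 17256 genes rose and 2957 fell by 2 h, and 4524 rose and 4085 fell by 4 h (edgeR adjusted p under 0.05). At 2 h the share of higher calls was 44.7% as fitted, 52% with DESeq2 (3048 and 2808), 49.6% with RLE size factors (2794 and 2840), 31.7% without a filter on low counts (1462 and 3150), 20.4% with total library size (685 and 2670) and 1% with scaling to ribosomal protein genes (38 and 3773). At 4 h the share was 52.5% as fitted, 57.3% with DESeq2 (5097 and 3793), 45.1% with only the groups compared (3444 and 4196), 34% with total library size (2274 and 4409) and 1.7% with scaling to ribosomal protein genes (127 and 7180).

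The comparison of the untreated lines at 0 h gave the background of the treated libraries. HCT116 cells had less FOXA1 than LS180 cells (2.58 ± 0.52 against 38.6 ± 1.78 CPM, 14.8-fold lower; edgeR adjusted p = 6.85e-14). They also had less FOXA2 (0.0424 ± 0.041 against 9.42 ± 0.573 CPM, 196-fold lower, log2 -7.61, or -8.81 without HCT116 0 h library 1) and less FOXA3 (1.80-fold lower). STAU1 was 1.18-fold higher in HCT116 (edgeR adjusted p = 0.000553) and STAU2 1.42-fold lower. CDX1, an intestinal transcription factor gene at 115 ± 5.26 CPM in LS180, had 0 counts in HCT116 and was at least 6669-fold lower against a floor of 3 counts over the group. On the same floor HIST1H1D was at least 7386-fold lower, the cadherin gene CDH11 5375-fold, NOX1, which encodes a colonic NADPH oxidase, 3844-fold, UGT1A8 3650-fold, CBR1 3497-fold, MYH13 3080-fold and CEACAM5, the carcinoembryonic antigen gene, 2896-fold. In the other direction MAGEB2 (146 ± 2.34 CPM in HCT116) was at least 7946-fold higher, HS6ST2 2840-fold, HTR7 1893-fold, BEX2 1406-fold, RAB31 1393-fold, IRX4 1205-fold and NR3C1, the glucocorticoid receptor gene, 1144-fold. RDX, at 136 ± 5.62 CPM in HCT116 and 1 count over the LS180 libraries, had a ratio of 22100 (exact 95% counting interval 3966 to 873000).

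Goblet genes were lower in HCT116 in 24 of 26 and higher in 1 (24 and 1 adjusted over the list alone), with AGR2 at 0.0499 against 946 CPM and REG4 at 0.0569 against 113 CPM. Their median log2 difference was -9.03, or -7.61 with genes at 0 counts set to their bound (camera adjusted p = 5.27e-16). Enterocyte genes were lower in 16 of 21 and higher in 4 (16 and 4 adjusted over the list alone), with the microvillus gene VIL1 at -11.71 and the intestinal cadherin gene CDH17 at -13.18. Their median was -5.27, or -5.21 at the bound. FOXA-dependent genes were lower in 12 of 16 and higher in 3 (12 and 3 adjusted over the list alone), with SHH at 0.39 against 80.8 CPM and GREB1 at 9.97 against 0.651 CPM. Their median was -6.43, or -6.33 at the bound. Xenobiotic genes were lower in 18 of 22 and higher in 3 (18 and 3 adjusted over the list alone), with CYP2J2 at -4.63 and ABCC2 at 6.79. Their median was -3.14, or -2.83 at the bound. Stem cell and Wnt target genes were lower in 18 of 22 and higher in 4 (18 and 4 adjusted over the list alone), with NKD1 at -4.81 and EPHB2 at -4.17, at a median of -2.85. These 5 camera calls held with an estimated correlation (adjusted p = 0.00157, 9.77e-05, 0.00191, 0.00262 and 0.0438).

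The other 4 lists called at 0 h were lost with it. Epithelial genes were lower in 14 of 22 and higher in 8 (14 and 8 adjusted over the list alone), with CDH1 at -2.53 and ESRP1 at 3.18. The epithelial list had a camera adjusted p of 0.00152 (adjusted p = 0.235 with an estimated correlation). Secretory pathway genes were lower in 33 of 40 and higher in 2 (33 and 2 adjusted over the list alone), with STT3B at -1.49. The secretory pathway list had a camera adjusted p of 0.0303 (adjusted p = 0.635 with an estimated correlation). This call was lost with RLE size factors (camera adjusted p = 0.0706) and with at least 1 CPM in every library of a group (0.061), which also ended the mitochondrial call (0.061). Mitochondrially encoded genes were higher in 12 of 13 and lower in 0 (12 and 0 adjusted over the list alone), with MT-ND6 at 1.95. The mitochondrial list had a camera adjusted p of 0.0399 (adjusted p = 0.635 with an estimated correlation). Immediate early genes were higher in 27 of 44 and lower in 14 (27 and 14 adjusted over the list alone), with DUSP5 at 3.44. The immediate early list had a camera adjusted p of 0.027 (adjusted p = 0.635 with an estimated correlation). Of 17256 genes 5819 were higher and 7343 lower in HCT116 (edgeR adjusted p under 0.05).

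The difference between the lines in the 4 h change, HCT116 minus LS180, tested whether transcripts were lost to different extents. FOXA1 gave no call (log2 difference 0.25, SE 0.355; edgeR adjusted p = 0.77), with an estimate that ranged from -0.38 without HCT116 4 h library 1 to 0.44 when single libraries were left out. FOXA3 fell less in HCT116 (1.81, SE 0.324; edgeR adjusted p = 0.000662), a call lost without LS180 4 h libraries 2 and 3 (1.49, edgeR adjusted p = 0.0524). STAU1 (-0.04, edgeR adjusted p = 0.819) and STAU2 (0.01, edgeR adjusted p = 1) gave no call. STAU1 was called lower with at least 1 CPM in every library of a group (-0.24, edgeR adjusted p = 0.0298) and without LS180 4 h libraries 2 and 3 (-0.30, 0.0494). The sign of both genes turned under other scalings, to 0.10 for STAU1 with scaling to ribosomal protein genes and -0.08 for STAU2 with RLE size factors. The cyclin-dependent kinase inhibitor gene CDKN1A (2.22, SE 0.192), the zinc finger gene ZNF440 (2.34, SE 0.116), CDCA4 (2.25, SE 0.131), FRAT2 (2.16) and EPHB3 (2.46, SE 0.422) were kept more in HCT116, with edgeR adjusted p from 1.53e-09 to 0.00044. ID3 (2.35) was also called (edgeR adjusted p = 0.00768) but not without HCT116 4 h library 1 (1.54, edgeR adjusted p = 0.0858) or LS180 4 h libraries 2 and 3 (0.168). ATP8B2 (2.06, edgeR adjusted p = 0.0143) was not called without LS180 0 h library 2 (0.0547), LS180 4 h library 1 (0.0512) or LS180 4 h libraries 2 and 3 (0.209), nor with an effective length offset (0.113). Its edgeR adjusted p ranged from 0.003 to 0.555, and its value was 2.87 without LS180 4 h library 2.

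Transcripts kept less in HCT116 included the Wnt inhibitor gene DKK1 (-2.44, SE 0.266), the BMP co-receptor gene RGMB (-2.56, SE 0.291) and the surface antigen gene GPA33 (-2.56, SE 0.512). The histone genes HIST2H3C (-2.56), HIST1H4K (-2.19, or -3.16 without HCT116 4 h library 1) and HIST1H2AD (-2.07) were also kept less, and HIST2H3C shares its sequence with another copy. For the 2 h change GPA33 (-1.58, edgeR adjusted p = 0.0906), HIST2H3C (-0.87, 0.57), ID3 (1.48, 0.141) and SNORA74A (-0.36, 0.971) gave no call. SNORA74A (-2.01, edgeR adjusted p = 0.0363) lost its call without any 1 of 8 libraries (0.0522 to 0.108). These were HCT116 0 h libraries 2 and 3, HCT116 4 h library 2, LS180 0 h libraries 1, 2 and 3, and LS180 4 h libraries 2 and 3. The call was lost as well with an effective length offset (edgeR adjusted p = 0.0535) and without both LS180 4 h libraries 2 and 3 (0.561). PDE2A and NNT were called on so few counts in one line that no fold is given.

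By list, camera called 13 of 27 at the preset correlation and 0 with an estimated one (smallest adjusted p = 0.266). Proliferation genes were kept more in HCT116 in 12 of 35 and less in 0 (15 and 0 adjusted over the list alone), with AURKA at 1.39, at a median of 0.20. The proliferation list had a camera adjusted p of 8.16e-05 (adjusted p = 0.539 with an estimated correlation). The p53 targets were kept more in 9 of 30 and less in 0 (14 and 0 adjusted over the list alone), with BTG2 at 1.76 and GADD45A at 1.58, at a median of 0.29. The p53 target list had a camera adjusted p of 0.000691 (adjusted p = 0.539 with an estimated correlation). KRAB zinc finger genes were kept more in 20 of 55 and less in 1 (23 and 1 adjusted over the list alone), with ZNF100 at 1.53, at a median of 0.48. The KRAB list had a camera adjusted p of 6.88e-05 (adjusted p = 0.431 with an estimated correlation). Histone genes were kept less in 8 of 19 and more in 0 (10 and 0 adjusted over the list alone) at a median of -1.24. The histone list had a camera adjusted p of 1.3e-07 (adjusted p = 0.539 with an estimated correlation). Genes that host snoRNAs were kept less in 4 of 18 and more in 0 (4 and 0 adjusted over the list alone), with SNHG12 at -0.72, at a median of -0.22. The snoRNA host list had a camera adjusted p of 6.88e-05 (adjusted p = 0.266 with an estimated correlation). The proliferation call was lost without HCT116 4 h library 3 (camera adjusted p = 0.0612).

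Of 17256 genes 2129 had a higher and 230 a lower 4 h change in HCT116 (edgeR adjusted p under 0.05), so 90.3% of calls were higher, but this split moved with the scaling and with single libraries. The counts were 1521 and 451 with RLE size factors (77.1%), 1719 and 662 with DESeq2 (72.2%), 1372 and 984 without a filter on low counts (58.2%), and 1213 and 2003 with at least 1 CPM in every library of a group (37.7%). With total library size they were 1835 and 128, and with scaling to ribosomal protein genes, which moved the median of all genes by 0.16, they were 1917 and 75. They were 1919 and 2536 without LS180 4 h library 1. Without HCT116 4 h library 1, 2 or 3 they were 1143 and 972, 1051 and 673, and 1079 and 830. TMM took another reference in these 4 fits. For ZNF440, CDCA4, CDKN1A, DKK1 and RGMB no alternative tried on the 4 h difference ended the call.

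Calls at 4 h overlapped between the lines. Of 5365 genes lower in LS180 and 4085 lower in HCT116, 3595 were shared, against 1270 for independent lists. Of 4591 and 4524 higher genes 3534 were shared, against 1204 for independent lists.

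**Figure D4:**
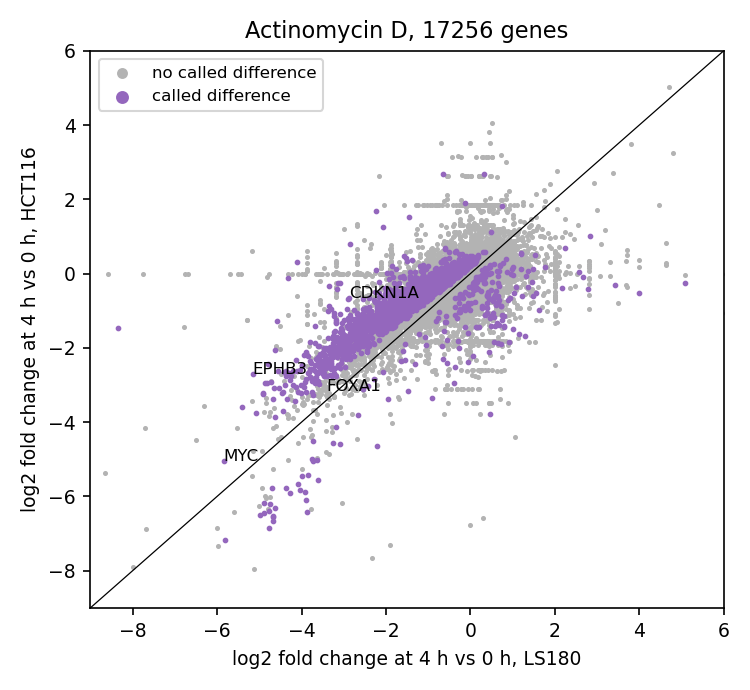
Log2 change at 4 h of actinomycin D in LS180 cells (x axis) and HCT116 cells (y axis) for 17256 genes (points; n = 3 libraries per group; 8 genes lie outside the axes). Purple points had an edgeR adjusted p under 0.05 for the line difference, where 2129 genes had a higher and 230 a lower change in HCT116.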

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

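The tests of the TMM reference library, of the LS180 4 h libraries and of the HCT116 libraries numbered 1 were chosen only after the results they bear on were seen. The genes and lists given first were picked because their 4 h change differed between the lines. This was by a test of the difference itself (edgeR for genes, limma's camera for lists).

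By gene, 2129 had a higher and 230 a lower change in HCT116 than in LS180. Among named genes, log2 differences above 0 were found for EPHB3 (2.46), ID3 (2.35), ZNF440 (2.34), CDCA4 (2.25), CDKN1A (2.22), FRAT2 (2.16), ATP8B2 (2.06), TNFSF9 (1.83), FOXA3 (1.81), MYC (0.81) and MT-CO3 (0.62). Differences below 0 were found for GPA33 and RGMB (both -2.56), HIST2H3C (-2.56), DKK1 (-2.44), HIST1H4K (-2.19), HIST1H2AD (-2.07), SNORA74A (-2.01), HIST1H2BO (-1.99), HIST1H2AH (-1.89), HIST1H2AI (-1.85), HIST1H3H (-1.52), HIST1H4B (-1.37) and MT-CYB (-0.66). That of GPA33 rests on few counts in HCT116 (0.112 CPM at 0 h and 0.0225 CPM at 4 h).

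By list, camera's calls had medians of 0.20 for proliferation, 0.29 for p53 target, 0.48 for KRAB zinc finger, 0.46 for immediate early, 0.15 for Staufen and decay factor and 0.12 for cholesterol genes. Medians below 0 were -1.24 for histone, -0.31 for mitochondrially encoded, -0.22 for snoRNA host, -0.17 for ribosomal protein, -0.082 for oxidative phosphorylation, -0.08 for secretory pathway and -0.059 for hypoxia genes. With an estimated correlation the smallest camera adjusted p of any list was 0.266. The mean of the histone list was -0.21. With scaling to ribosomal protein genes the medians of 4 lists changed sign, to 0.01 for ribosomal protein, 0.08 for secretory pathway, 0.09 for oxidative phosphorylation and 0.12 for hypoxia genes. With total library size the last 3 became 0.01, 0.01 and 0.04.

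The cholesterol list (camera adjusted p = 0.00294; range over alternatives up to 0.594) was not called without HCT116 4 h library 1 (0.131), 2 (0.211) or 3 (0.25) or LS180 4 h library 1 (0.594). Nor was it called without a filter on low counts (camera adjusted p = 0.118) or with at least 1 CPM in every library of a group (0.276), where its median was -0.08. The Staufen and decay factor list (camera adjusted p = 0.007; range over alternatives up to 0.355, without LS180 4 h libraries 2 and 3) was not called without HCT116 4 h library 2 (0.211) or 3 (0.25). Its call was also lost without a filter on low counts (camera adjusted p = 0.0829) and with at least 1 CPM in every library of a group (0.187), where its median was -0.04. The immediate early list (camera adjusted p = 0.0413; up to 0.318 with an effective length offset) was not called without HCT116 0 h library 2 (0.0565), HCT116 4 h library 1 (0.173), or LS180 4 h library 2 (0.0854) or 3 (0.0544). The mitochondrial list (camera adjusted p = 0.00921) was not called without HCT116 4 h library 3 (0.0612) or with at least 1 CPM in every library of a group (0.052), and the oxidative phosphorylation list (0.000316) not without LS180 4 h library 3 (0.0926). The hypoxia list (camera adjusted p = 0.0452) was not called without HCT116 0 h library 2 (0.0689) or 3 (0.11), LS180 0 h library 1 (0.0531) or 3 (0.0679), or LS180 4 h library 2 (0.0854) or 3 (0.109). Without both LS180 4 h libraries 2 and 3 camera's adjusted p was 0.968 for oxidative phosphorylation, 0.146 for mitochondrial, 0.104 for hypoxia, 0.0774 for ribosomal protein and 0.0668 for immediate early genes. Scaled to ribosomal protein genes, the oxidative phosphorylation (camera adjusted p = 0.229), secretory pathway (0.148) and hypoxia (0.138) calls were lost, and with total library size the hypoxia call (0.0802).

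The first pattern weighed was that 90.3% of the line difference calls were higher in HCT116. TMM scales each library against a reference library, here LS180 4 h library 1. With each of the 18 libraries as reference in turn the share ran from 42.4% to 93.4%, under 60% with 6 of them, so the direction of the calls may come from the reference. Among calls of 2-fold or more the share ran from 56.2% to 82.8%, which leaves the reference open as a cause of part of that imbalance. LS180 4 h libraries 2 and 3 stood apart from library 1 (chi-square per degree of freedom 57.2 and 109, against 15.7 between them). Leaving them out lowered the share among calls of 2-fold or more by at most 2.4 points with any of 16 references. The bound of 5 was set afterwards, and a share can hold as calls are lost, so these libraries stay open. With the reference as fitted the share was 81%. The 57.4% without them came with another reference, HCT116 2 h library 1. A difference between the lines in how fast transcripts are lost stays open, as untested apart from the scaling.

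Other splits of the libraries were counted for each comparison of groups of 3. For the line difference, 6 of 40 splits gave as many calls as the real 2359, the highest other 10442, so chance is not excluded by this count. All 5 of the other splits as large kept or swapped one line whole, and the highest of the 29 that mixed both lines called 1 gene. The large counts thus point to the structure of the samples, in which each line has its own strong 4 h change. For the other comparisons the 10 possible splits are too few for a share under 0.05. The real counts were 6450 and 9956 in LS180 at 2 and 4 h, 5346 and 8609 in HCT116, and 13162 between the lines at 0 h. In each 1 split, the real one, reached its count, and the highest others were 1, 1, 0, 1 and 0.

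A further pattern was that the HCT116 libraries numbered 1 stood apart from numbers 2 and 3 at each time (chi-square per degree of freedom 21.7 to 37.7, against 3.9 to 8.3 between the others). Of 9997 genes at 5 CPM or more, 21 were at least 1.5-fold higher and 5 lower in number 1 at each time, among them ID2 (62.1 CPM against 25.9 and 24.4 at 0 h), ID3, ID1, AQP3 and AHNAK2 higher. LS180 RNA in these libraries is argued against, since 89 genes that HCT116 nearly lacked stood at no more than 0.0292% of their LS180 level. Depth is argued against too, since at 2 h number 1 had 53.7 M counts, fewer than either of the others, yet 21041 genes with a count against 20633 and 20626. No biological explanation was tested, because the labels give the libraries only a number. A separate culture or day, not on the labels, stays open.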

How the results depend on the processing

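The line difference at 2 h and the fits without the HCT116 libraries numbered 1 or LS180 4 h libraries 2 and 3 were chosen after seeing the data. For results that changed, the cause was not tested, except that a filter or a left-out library changes what is fitted. TMM also chose another reference without LS180 2 h library 2, HCT116 2 h library 2 or 3, any 4 h library, or both LS180 4 h libraries 2 and 3, so changes in those fits may come from the reference. Of single-gene results, 874 kept their direction and side of the threshold when single libraries were left out, 28 lost and 2 gained a call and 8 turned sign. RLE size factors gave 138, 0, 1 and 1, DESeq2 137, 0, 2 and 1, an effective length offset 132, 5, 0 and 3, total library size 114, 7, 0 and 1, and scaling to ribosomal protein genes 86, 6, 0 and 9. Of list results, 1193 kept their side of the threshold when single libraries were left out and 27 lost and 18 gained a call. Camera's direction turned in 43 (0 of them called lists) and the median in 82 (13 called), while an estimated correlation kept 122 and ended 66. The STAU1 fall with siSTAU1 and the FOXA1 fall in LS180 at 4 h held under every alternative run. With n = 2 per siRNA group the simulated fit recovered 80.6% of 1.5-fold changes, and smaller ones such as that of FOXA1 were not simulated.

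The FOXA1 change with siSTAU1 was 0.14 with DESeq2, 0.17 with an effective length offset and 0.14 without a filter on low counts, and 0.13 to 0.16 when single libraries were left out, all without a call. With single libraries left out, genes higher with siSTAU1 numbered 1968 to 3102 and lower 2105 to 3292, and with an effective length offset 2159 were lower. Genes higher in LS180 at 2 h numbered 5189 with at least 1 CPM in every library of a group, 4927 with DESeq2, 4921 without a filter, 3893 with only the groups compared, 4863 with RLE size factors, 55 with scaling to ribosomal protein genes, and 1095 with total library size. They numbered 1478 to 4309 with single libraries left out. At 4 h 132 were higher and 10737 lower with scaling to ribosomal protein genes, and 1893 higher with total library size. In HCT116 at 2 h 1462 were higher without a filter, 38 with scaling to ribosomal protein genes, 685 with total library size and 1032 to 2083 with single libraries left out. At 4 h 127 were higher and 7180 lower with scaling to ribosomal protein genes, and 2274 higher with total library size.

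Line difference calls were 1213 higher and 2003 lower with at least 1 CPM in every library of a group, 905 and 68 for the 2 h change, 1372 and 984 without a filter, and 524 and 466 without LS180 4 h libraries 2 and 3, or 1103 and 145 with the TMM reference kept. Lower calls were 662 with DESeq2, 451 with RLE size factors, 75 with scaling to ribosomal protein genes and 128 with total library size. With single libraries left out, 1051 to 2101 were higher and 136 to 2536 lower. The FOXA1 line difference turned to -0.067 with an effective length offset, -0.053 at 2 h, -0.041 without the HCT116 libraries numbered 1 and -0.24 without LS180 4 h libraries 2 and 3, and ran from -0.38 to 0.44 with single libraries left out. NEAT1 in HCT116 at 2 h turned to -0.59 with an effective length offset. With scaling to ribosomal protein genes STAU1 became -0.080 and -0.34 in LS180 and -0.090 and -0.24 in HCT116 at 2 and 4 h, STAU2 -0.13, -0.30, -0.046 and -0.12, and the STAU1 line difference 0.10, or 0.031 with total library size. The STAU2 line difference was -0.18 with at least 1 CPM, -0.078 with DESeq2 and with RLE size factors, -0.062 with an effective length offset, -0.14 without a filter, -0.037 without LS180 4 h libraries 2 and 3, and -0.21 to 0.070 with single libraries left out.

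Replicate numbers are shared by the groups, but deviations of same-numbered libraries from their group means correlated at -0.06 in the siRNA experiment, -0.09 to 0.07 in LS180 and 0.08 to 0.33 in HCT116. The HCT116 values hint at shared numbers and were all over 0.1 between 2 and 4 h (0.26, 0.14 and 0.11), but not all between 0 h and either time, so the numbers were not taken to pair samples. With the replicate block 3560 genes were higher and 3504 lower with siSTAU1, 3038 and 4381 in LS180 at 2 h, 5002 and 5608 at 4 h, 3172 and 3242 in HCT116 at 2 h, 5031 and 4321 at 4 h, 5862 and 7409 between the lines at 0 h, and 2506 and 310 for the line difference. The block changed no call of a named gene, gained 4 list calls and ended 2.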

Other observations

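The mitochondrial list was fixed earlier, but MT-ND6 was singled out after its values were seen. The tests of 3' UTR words, mRNA turnover and GC content were written before their results.

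Mitochondrially encoded mRNAs, only 0.05 to 0.16% of counts, parted into opposite directions under actinomycin D. MT-ND6, the mRNA encoded on the other strand from the rest, fell 6.07-fold by 2 h and 13.4-fold by 4 h in LS180 cells, from 2.66 ± 0.248 to 0.435 ± 0.156 and 0.198 ± 0.057 CPM. In HCT116 cells it fell 7.12-fold and 20.2-fold from 10.3 ± 2.65 CPM (edgeR adjusted p from 1.03e-11 to 3.89e-08; n = 3). At 4 h 7 of 13 members rose and 3 fell in LS180, with MT-ND4 at 1.23, MT-CYB at 1.20 and MT-CO1 at 1.01 higher and MT-ND1 (-0.54) and MT-ND3 (-0.32) lower (7 and 3 adjusted over the list alone). In HCT116 7 rose and 4 fell, with MT-CO3 at 1.12 higher and MT-ATP8 (-0.98), MT-ND1 (-0.64) and MT-ND2 (-0.53) lower (8 and 4 adjusted over the list alone). The list medians of 0.50 and 0.33 were not called by camera (adjusted p = 0.121 and 0.662). With scaling to ribosomal protein genes they became -0.04 and -0.06, while the test pointed up and called the LS180 list (camera adjusted p = 0.0283; 0.481 in HCT116).

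The pattern weighed for the siRNA experiment was the large number of genes lower with siSTAU1, for which an effect of the siRNA on other mRNAs is a candidate explanation. A search of all 7-base words in the 3' UTRs of genes on odd-numbered chromosomes gave GTGATGC as the word with the lowest score (mean residual difference -0.14). On even-numbered chromosomes the 490 genes of 5172 that hold it were lower by a difference of -0.09 (SE 0.019; one-sided permutation p = 0.0001, the smallest 10000 permutations can give; rank 1 of 13820 words). GTGATGC was in 15% of 3072 lower, 5.1% of 3078 higher and 8% of uncalled genes, and 23.4% of 107 lower by 2-fold or more. The shares cover 12117 searched genes of 14060, those that chose the word included, and do not test it. ADAM19, GATD1 and VMA21 held it, but not LCK, PRDM8, KMT5A or KRT4. A STAU1 siRNA with this seed needs the word in STAU1, which held it (8 of 10 transcripts). Of coding genes 19.3% hold it, so this is a weak sign. A seed-type effect of the siRNA may thus account for part of the lower genes. The siRNA sequences are not given in the sources used here, and a microRNA with the same seed stays open. Most lower genes that could be searched lacked the word, and the higher genes are left without an account.

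For the genes higher with siSTAU1, the highest-scoring word on odd-numbered chromosomes, ATTACAA, gave a difference of 0.045 on even-numbered ones (SE 0.016; one-sided permutation p = 0.0015; rank 168). That is under the 0.05 set in advance by less than its SE, so an effect of the control siRNA's seed is undecided. GC content and length are argued against as the cause of the higher goblet, FOXA-dependent and xenobiotic lists, since the joint median of their 53 genes was 0.297 (SE 0.061) before and 0.241 (SE 0.047) after the trend, which explained 7.6% of the variance, was taken out.

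A hypothesis that genes higher with siSTAU1 carry short-lived mRNAs in LS180, as direct targets of a decay factor might, was not borne out. Their median 4 h change under actinomycin D was 0.179 above that of expression-matched genes that were not called (SD 0.012; 3174 genes; one-sided permutation p = 1), so they were lost less than matched genes. The genes lower with siSTAU1 were lost more (-0.173, SD 0.012; 3158 genes; one-sided permutation p = 0.0001), a mirror of this that was left unexplained. The comparison sets polyA libraries beside total RNA libraries, and genes are not independent replicates.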
